A study of Caenorhabditis elegans with 36 samples.

How the data were processed

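RNA was measured in whole animals of the nematode C. elegans at 3 stages. Poly(A) RNA-seq libraries were made from embryos and L1 larvae (first larval stage) of the wild type N2 and of animals labelled xnp-1, and from L4 larvae (last larval stage) labelled N2, xnp-1, gsox-1 and xnp-1;gsox-1, with 3 libraries labelled as biological replicates in each of the 8 groups. xnp-1 is the worm orthologue of the chromatin remodeller ATRX. Per the labels, embryos came from hypochlorite-treated adults grown at 20 °C, L1 larvae were such embryos kept for about 11 h in M9 buffer, and L4 larvae grew at 25 °C. Embryo and L1 libraries were sequenced at one centre and L4 libraries at another, so the tables were fitted apart and no L4 library was compared directly with an embryo or L1 library. The genotype is labelled xnp1 for embryos and L1 larvae, while the study's design text calls the same animals a knockdown. The text keeps the labels as they stand.

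The deposited poly(A) tables hold raw counts per gene for the WS280 canonical gene set, with no normalization by the authors. Per the file headers, featureCounts 2.0.1 made the embryo and L1 table with strand-specific counting of fragments and a minimum mapping quality, and featureCounts 2.0.6 made the L4 table with paired-end mode but without the option that counts read pairs, so both mates of a pair may be counted there. An L4 total is therefore not on the scale of an embryo or L1 total. Per the submitters' processing notes, reads passed FastQC, Trim Galore, STAR, SAMtools and featureCounts, with no versions given for the first 4. Another deposited table, named by the authors as counts of 22G-RNAs (small RNAs bound by Argonaute proteins) and un-normalized, holds raw counts per feature for WS279 in embryo and L1 columns. Its counting rule is not stated. Its values follow the poly(A) counts column by column, so it is called here the table named for 22G-RNAs and its values are not read as small RNA counts.

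Each poly(A) table lists 46926 genes, of which 44114 have a name in the gene name table used. Coordinates are those of the deposited tables (assembly WBcel235). Totals per library ran from 29896459 to 41520291 fragments in embryos and L1 larvae, from 39004451 to 45391494 reads at L4, and from 72010750 to 102105493 in the table named for 22G-RNAs. Where a group had no count, the fold was computed against a floor of 3 counts over the group and given as a lower bound. Bounds and intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

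Changed genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, a 4-group design, robust quasi-likelihood fit and F test, two-sided), with a Benjamini-Hochberg adjusted p under 0.05 over all genes that passed the filter. The p-values of edgeR, DESeq2 and fry measure the spread between samples labelled biological replicates. Those of camera, overlaps, chromosomes, gene sets drawn at random and correlations are computed over genes. Fold changes are log2 with the standard error (SE) of the fit. Levels are CPM values (counts scaled to a common library size with TMM, from edgeR), with the SD over 3 libraries. The comparisons, tests, alternatives, 34 gene lists and the rule for named genes were fixed before the data were examined. That rule took, per direction, the 12 genes with the largest change in each poly(A) comparison of a labelled genotype with N2. It took 6 in the other contrasts and in the table named for 22G-RNAs. They had to pass the threshold, reach a mean log2 CPM of at least 1 (3 in the table named for 22G-RNAs) and have libraries of the 2 groups that did not overlap. Chance alone separates 3 libraries from 3 in 10% of unchanged genes. Genes with a name of letters and a number came first, except in the table named for 22G-RNAs. The rule added xnp-1, gsox-1 and up to 4 members of each list with the smallest adjusted p. Where fewer are printed, they are the top of the ranking.

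Lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01, adjusted over 34 lists. Camera asks whether a list's genes moved more than the other genes. At the preset correlation its p-value rests on the spread between genes. It does not measure how far a list as a whole varies between replicates. Camera with a correlation estimated per list, and fry, were run beside it. Fry tests whether a set's genes move, on balance, one way and does not compare them with other genes. The lists cover chromatin (heterochromatin factors, synMuv B genes, histones, histone H3.3), germline (P granule, meiosis, oocyte, sperm, Argonaute and ERI pathways), somatic tissues (intestine, muscle, pharynx, neurons, cilia, chemoreceptors, glia, hypodermis, coelomocytes and vulva), cuticle and moulting, early embryonic fate, stress and immunity, metabolism, ribosomal proteins, DNA damage, dosage compensation, vitellogenins and starvation. They were written from general knowledge. Genes of families with near-identical members (msp, nspd, vit, col, his) can share reads, so values of single members of these families are uncertain.

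The chromosomes of changed genes and the overlaps of changed genes between comparisons were tested with Fisher's exact test (two-sided, adjusted over 96 and 16 tests). The 3 L4 comparisons with N2 share the same N2 libraries, so 20 sets of unchanged groups against those libraries were simulated. Correlations across genes used 100000 permutations.

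Replicate numbers in the labels were checked for pairing by the correlation, over genes, of same-numbered libraries' deviations from their group means. All 3 pairs exceeded 0.1 for L1 xnp-1 and L1 N2 (0.901, 0.841 and 0.877), for N2 embryos and N2 L1 (0.36, 0.183 and 0.39), for N2 embryos and L1 xnp-1 (0.306, 0.129 and 0.384), for L4 xnp-1;gsox-1 and N2 (0.844, 0.606 and 0.789), for L4 xnp-1 and N2 (0.432, 0.259 and 0.42) and for L4 xnp-1;gsox-1 and xnp-1 (0.492, 0.373 and 0.474). These numbers were taken to pair the libraries. The pairing comes from the data, since the labels state no shared batch. The other groups share only a number. Within the L4 set, the mitochondrial share of counts was 5.52% in xnp-1;gsox-1 replicate 1 and 4.13% in N2 replicate 1, and 1.42% to 2.43% in the other 10 libraries. No 2 replicates of a group were duplicates of each other by a chi-squared comparison of their counts. Libraries of different groups were not compared in this way.

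The steps were tested on simulated data with 200 changed genes. At 2-fold, 41.8% of changed genes were found in the embryo comparison, 34.8% at L1, 3% for the difference between stages, 25.8% for N2 L1 against N2 embryos, 11.9% for L4 xnp-1, 13.4% for gsox-1, 7.7% for xnp-1;gsox-1, 11.9% for xnp-1;gsox-1 against xnp-1, 21.2% against gsox-1 and 1.5% for the L4 interaction. At 4-fold these shares were 81.8%, 86.2%, 69.2%, 84.8%, 76.9%, 84.8%, 80.3%, 75.8%, 84.6% and 30.3%. At 1.5-fold they were at most 3%. Between 1 and 6 unchanged genes were called. A list shifted by 0.5 log2 was found in 10 of 10 comparisons, with no other list called. Each gene was drawn independently there, with no structure shared between libraries. False calls from genes that move together or from such structure are thus not covered. In the table named for 22G-RNAs, 92.4% and 83.3% of genes changed 4-fold were found in embryos and L1.

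Alternatives changed 1 choice at a time, but for the replicate block with only the groups compared, which changes 2. They were scaling by size factors (RLE) or by library totals, DESeq2 1.42.0, no or a stricter count filter, the replicate number as a block, a fit of only the groups compared, a fold minimum, and leaving out each library. Chosen after seeing the data were an age score (mean log2 CPM of the genes higher in N2 L1 than in N2 embryos minus that of the genes lower, centred per stage) as a covariate, the replicate block with only the groups compared, and leaving out the 2 L4 libraries of highest mitochondrial share. TMM put the median change of all genes at -0.16 (log2) for L4 xnp-1, where size factors gave -0.08 and totals -0.09. For N2 L1 against embryos the median was 0.10, and 0.19 with totals. For the stage difference it was -0.01, -0.05 with size factors and 0.07 with totals. For the L4 interaction it was 0.15, 0.07 with size factors and 0.17 with totals. For xnp-1;gsox-1 it was 0 against N2 (0.01 with size factors, 0.09 with totals) and 0.01 against gsox-1 (0.01 and 0.09). Against xnp-1 it was 0.09, 0.03 and 0.12, so that changes of this size are not told from the scaling. The small RNA reads themselves were not analysed here.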

Results

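Poly(A) RNA was profiled in 24 libraries, 3 in each of 8 groups. Totals were 41418691, 33405854 and 29896459 fragments for N2 embryos (replicates 1 to 3) and 38764823, 41520291 and 40828436 for xnp-1 embryos. They were 33792030, 34538878 and 39473088 for N2 L1 larvae and 34779480, 34917680 and 40647115 for xnp-1 L1 larvae. L4 totals were 41178079, 42781986 and 41532132 reads for N2 and 39004451, 39392872 and 42968495 for xnp-1. They were 43010645, 42207473 and 39997100 for gsox-1 and 41944865, 45391494 and 40295080 for xnp-1;gsox-1. After filtering, 17687 genes were tested in embryos and L1 larvae and 17492 at L4. The first principal component held 80.7% of the variance among embryo and L1 libraries. Among L4 libraries it held 62%, with the xnp-1 libraries at 143.8 to 173.5 and the other 9 libraries at -74.4 to -40.4.

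xnp-1 (WBGene00006961, chromosome I, 4665933 to 4671738) was lower in embryos labelled xnp-1, at 131.5 ± 7.72 CPM against 401.1 ± 28.02 in N2 (SD, n = 3 each; log2 change -1.61, SE 0.136, edgeR adjusted p = 5.98e-05). In L1 larvae labelled xnp-1 it stood at 170.4 ± 6.62 CPM against 249.1 ± 33.3 (-0.55, SE 0.134, edgeR adjusted p = 0.135). It was called there by DESeq2 (adjusted p = 0.00629) and in a fit of the L1 libraries alone with the replicate block (adjusted p = 0.0064, edgeR), but not with the block in the fit of all groups (-0.54, adjusted p = 0.0965, edgeR). At L4 it was 46.01 ± 5.73 CPM in libraries labelled xnp-1 and 29.3 ± 7.64 in those labelled xnp-1;gsox-1, against 75.5 ± 13.3 in N2 (-0.72, SE 0.206, and -1.36, SE 0.209; edgeR adjusted p = 0.0131 and 0.0124). The xnp-1 call was lost without N2 replicate 3 (-0.58, adjusted p = 0.0538, edgeR) and without xnp-1 replicate 1 (-0.62, adjusted p = 0.0628, edgeR). That of xnp-1;gsox-1 was lost without its replicate 2 (-1.35, adjusted p = 0.071, edgeR) and in a fit of only the groups compared (-1.34, adjusted p = 0.122, edgeR). Libraries labelled gsox-1 held 92.2 ± 4.92 CPM of xnp-1 (0.29, adjusted p = 0.882, edgeR).

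gsox-1 (WBGene00009365, chromosome II, 10174648 to 10180040) was not reduced in the L4 libraries labelled gsox-1, at 78.5 ± 3.55 CPM against 56.9 ± 12.7 in N2 (SD, n = 3; 0.46, SE 0.246, edgeR adjusted p = 0.882). It was not reduced in those labelled xnp-1;gsox-1 either (70.5 ± 24.7 CPM, 0.31, adjusted p = 0.701, edgeR). All 3 libraries labelled gsox-1 lay above all 3 N2 libraries. The labels name no allele, so the level of the transcript does not show whether the gene was mutated. These are called the libraries labelled gsox-1 throughout. In L4 libraries labelled xnp-1, gsox-1 rose to 162.6 ± 14.9 CPM (1.51, SE 0.25, edgeR adjusted p = 0.000443). It was 312.1 ± 60.95 CPM in xnp-1 embryos against 217.6 ± 20.2 in N2 (0.52, adjusted p = 0.242, edgeR) and 176.6 ± 21.7 against 127.2 ± 24.2 in L1 larvae (0.47, adjusted p = 0.592, edgeR). In the fit of the L1 libraries alone with the block it was called higher (0.48, adjusted p = 0.0055, edgeR), and with the block in the fit of all groups it was not (0.48, adjusted p = 0.433, edgeR).

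**Figure D1:**
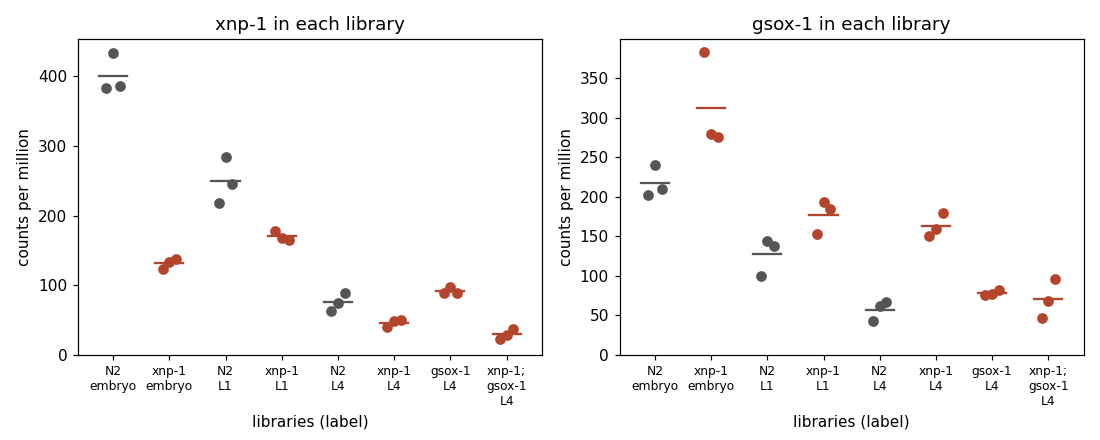
Level of xnp-1 (left) and gsox-1 (right) in CPM in each library (points) of 8 groups, with bars at the group means. xnp-1 means 401.1 in N2 and 131.5 in xnp-1 embryos, and gsox-1 in L4 libraries labelled gsox-1 (75.7 to 82.5) lies above N2 (42.6 to 66.7).

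In xnp-1 embryos against N2 embryos, 76 genes rose and 121 fell at edgeR adjusted p under 0.05. sdha-2, a paralogue of a succinate dehydrogenase subunit (WBGene00016392, chromosome I, 10683270 to 10685587), rose by 2.39 (log2, SE 0.188) to 173.5 CPM against 33.1 in N2 (n = 3 each). The RNase H family gene rnh-1.3 rose by 3.35 (SE 0.425; 9.64 against 0.946 CPM), and the ABC transporter gene abt-5 by 2.33. The centromeric histone H3 paralogue cpar-1 rose by 1.90 and the small nuclear RNA activating complex gene snpc-1.2 by 1.83 (67.9 against 19.1 CPM). fbxa-192, lsl-1, zhp-2, atg-10, set-31, enu-3.2 and the Argonaute gene wago-4 rose by 1.83, 1.81, 1.73, 1.54, 1.53, 1.45 and 1.41. The aspartyl protease gene asp-8 changed by -3.67 (SE 0.438; 0.0974 against 1.27 CPM), the peroxisomal acyl-CoA oxidase genes acox-1.4 and acox-1.3 by -2.82 and -2.42, the cuticle collagen gene col-92 by -2.43 and the lectin gene clec-76 by -2.20. nspg-7.2, oac-1, pcp-4, nceh-1, spig-10, pgp-9 and oac-20 changed by -3.36, -2.63, -2.38, -2.13, -2.12, -2.03 and -1.99.

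By list, 9 lists rose and 9 fell with camera in embryos, and no list was called with an estimated correlation. Argonaute and small RNA pathway genes rose (4 of 45 over all genes tested, 5 adjusted over the list alone; median 0.25, camera adjusted p = 1.3e-06 and adjusted p = 0.704 with an estimated correlation). Among them ppw-2 rose by 1.36, the Piwi gene prg-1 by 1.16 (SE 0.161) and the nuclear RNAi gene nrde-2 by 0.80. Meiosis genes moved up as a list (median 0.56, camera adjusted p = 8.71e-10 and adjusted p = 0.704 with an estimated correlation), with no member of 28 past the threshold over all genes and 5 higher adjusted over the list alone. The cohesin gene rec-8 was at 0.93 (adjusted p = 0.0632, edgeR). Lists of synMuv B repressors (median 0.30, 1 of 17 called: lin-13 at 0.88), DNA damage genes (0.30), early embryonic fate genes (0.26), heterochromatin factors (0.23), replication-dependent histones (0.35), P granule genes (0.21) and dosage compensation genes (0.19) also rose. Their camera adjusted p ran from 4.59e-05 to 0.0395, and from adjusted p = 0.73 to 0.769 with an estimated correlation.

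Several lists of differentiated tissues were lower in xnp-1 embryos. An age difference stays open for these lists and for those that rose, as given below. Camera did not call sensory cilia (median 0.055), glia (0.101), hypodermis (0.062), coelomocyte and vulval (0.044) or chemoreceptor genes (-0.21, 1 of 364 rose), at adjusted p from 0.139 to 0.929. Neuropeptide genes had a median of -0.48 (1 of 105 fell over all genes and 1 adjusted over the list alone, nlp-25 at -3.91, camera adjusted p = 8.71e-10 and adjusted p = 0.73 with an estimated correlation). Collagens had -0.38, or -0.37 with zero-count genes at their bounds (2 of 148 fell, col-92 and col-107, and 22 adjusted over the list alone, camera adjusted p = 5.91e-06 and adjusted p = 0.704 with an estimated correlation). Innate immunity genes had -0.47 (3 of 34 fell, 4 adjusted over the list alone; clec-67 at -1.81, irg-3 at -1.94 and irg-1 at -1.22, camera adjusted p = 1.8e-05 and adjusted p = 0.704 with an estimated correlation). Neurotransmitter identity genes (-0.46, 7 of 28 lower adjusted over the list alone), body wall muscle (-0.24), moulting (-0.26), pharynx (-0.22), intestine (-0.33, pgp-3 at -1.13) and pan-neuronal genes (-0.13) also fell. Camera adjusted p ran from 5.91e-06 to 0.0191, and from adjusted p = 0.704 to 0.73 with an estimated correlation. The pharynx list held 1 riser over all genes, the intermediate filament gene ifb-1 (0.82). The embryo count fell to 53 without N2 replicate 1, 90 without N2 replicate 3, and 87, 78 and 83 without xnp-1 replicates 1, 2 and 3. It was 590 with DESeq2, 580 in a fit of the embryo libraries alone, and 659 with an age score as a covariate.

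In xnp-1 L1 larvae against N2 L1 larvae, 64 genes rose and 21 fell (edgeR). prg-1, the Piwi Argonaute gene (WBGene00004178, chromosome I, 7585329 to 7588367), rose by 1.99 (SE 0.165) to 193.2 ± 21.2 CPM against 48.6 ± 10.1 (SD, n = 3 each). sdha-2 rose by 2.55 (SE 0.19) to 110.2 ± 12.5 against 18.9 ± 4.87. rnh-1.3, fbxa-192, cpar-1, abt-5, bath-29, snpc-1.2, zhp-2, puf-8, bath-30 and enu-3.2 rose by 2.54, 2.50, 1.95, 1.94, 1.87, 1.71, 1.64, 1.59, 1.59 and 1.58. Of these, puf-8 encodes a germline RNA-binding protein. acox-1.4 changed by -2.31 (SE 0.39), the acid phosphatase gene pho-11 by -1.74, gstk-1 by -1.43, nceh-1 by -1.35, the ribose 5-phosphate isomerase gene rpi-1 by -1.14, lelo-2 by -1.10, ctsa-4.2 by -0.96 and clec-67 by -0.78. The numbers pair these libraries, and a fit of the L1 libraries alone with the replicate block (the paired fit) called 2002 genes (610 higher, 1392 lower), among them all 85. Most called genes were thus higher without the pairing and lower with it. The overlaps, chromosomes, genes shared with embryos and neighbouring genes below rest on the calls without the pairing. With the block in the fit of all groups, nceh-1 and ctsa-4.2 missed the threshold (adjusted p = 0.0517 for each, edgeR).

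Meiosis genes rose as a list in L1 larvae (1 of 28 called over all genes and 4 adjusted over the list alone). rec-8 rose by 1.39 (SE 0.22), and the list had a median of 0.47 (camera adjusted p = 2.14e-11 and adjusted p = 0.695 with an estimated correlation). Argonaute genes rose too, with 4 of 45 called over all genes and 4 adjusted over the list alone: prg-1, wago-4 at 1.15, ppw-2 at 0.88 and nrde-2 at 0.60. Their median was 0.20 (camera adjusted p = 3.82e-08 and adjusted p = 0.695 with an estimated correlation). Replication-dependent histones (median 0.51), oocyte genes (0.32), P granule genes (0.26), intracellular pathogen response genes (0.26), synMuv B genes (0.23), DNA damage genes (0.21) and heterochromatin factors (0.21) rose at camera adjusted p from 7.55e-07 to 0.0095 (adjusted p = 0.695 with an estimated correlation for each). Of 28 histones, 5 were called adjusted over the list alone. Neuropeptides fell (median -0.34, 0 of 105 called over all genes by edgeR and 42 lower in the paired fit, camera adjusted p = 2.17e-11 and adjusted p = 0.695 with an estimated correlation). Xenobiotic and oxidative stress genes fell (median -0.44, 4 of 35 adjusted over the list alone and 16 in the paired fit, camera adjusted p = 6.79e-09 and adjusted p = 0.127 with an estimated correlation). It was the 1 list that fry called (adjusted p = 0.0378). Intestine (-0.40), starvation response (-0.34), ribosomal proteins (-0.18), neurotransmitter identity (-0.18), innate immunity (-0.14, 1 of 34 called) and body wall muscle (-0.11) fell at camera adjusted p from 7.55e-07 to 0.0269, and at adjusted p from 0.695 to 0.71 with an estimated correlation. Collagens were at -0.09 (camera adjusted p = 0.167), with 2 higher and 30 lower of 145 in the paired fit. The L1 count was 55 without N2 replicate 1, 35 without N2 replicate 2, 36 without xnp-1 replicate 2 and 38 without xnp-1 replicate 3. It was 234 with DESeq2, 13 in an unpaired fit of the L1 libraries alone and 245 with the age score.

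Tested gene by gene, the difference in the effect of xnp-1 between stages called 0 genes with edgeR (454 at an unadjusted p under 0.05) and 3 with DESeq2. Those 3 were xnp-1 itself (1.03, adjusted p = 0.00212, DESeq2), ZK896.1 (1.58) and F28H6.8 (-2.34), the last 2 named after their values were seen. In edgeR xnp-1 had a difference of 1.06 (SE 0.189, adjusted p = 0.747), less reduced in L1 than in embryos, and gsox-1 one of -0.05 (SE 0.258). In simulated data this test found 3% of genes that differed 2-fold, so the count of 0 does not show that no gene differed. Camera called 9 lists on the difference, 7 of them higher in L1 than in embryos, among them collagens (median 0.37, adjusted p = 4.35e-05), innate immunity (0.39, adjusted p = 0.00342), neurotransmitter identity (0.24), oocyte (0.08), histones (0.21), moulting (0.18) and pharynx genes (0.21). The other 2 were lower, ribosomal proteins (-0.18, adjusted p = 1.12e-08) and xenobiotic genes (-0.21, adjusted p = 0.000341). With library totals as the scaling the medians were 0.167 for oocyte, -0.094 for ribosomal and -0.121 for xenobiotic genes, with no change of sign among the 9. None held with an estimated correlation, at adjusted p from 0.867 to 0.917 with an estimated correlation.

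The changes at both stages overlapped gene by gene, in groups that share no library. The numbers pair N2 embryos with both groups of L1 larvae, so the stages are not fully independent, as the expected counts assume. Of the genes that rose in embryos, 49 also rose in L1 (0.275 expected if independent), and 12 fell at both stages (0.144 expected), with none in opposite directions. Two-sided Fisher's exact tests gave p = 2.12e-111 and 1.68e-21 (adjusted p = 3.38e-110 and 5.36e-21 over 16 tests). Across all 17687 genes the log2 changes correlated at Pearson 0.47 and Spearman 0.525, where genes are not independent replicates. With the age score of each stage as covariates the Pearson value was 0.278, and that score was lower in xnp-1 by 0.37 in embryos and by 0.35 in L1. The 49 genes include sdha-2, rnh-1.3, abt-5, cpar-1, snpc-1.2, zhp-2, prg-1, wago-4, ppw-2 and nrde-2. Followed at L4 after these calls were known, 41 of the 47 that could be tested rose in libraries labelled xnp-1 (median 1.65), and 9 rose in those labelled xnp-1;gsox-1 (median 0.64, 43 of 47 above 0). None was called in those labelled gsox-1 (edgeR; median -0.05, 20 above 0).

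**Figure D2:**
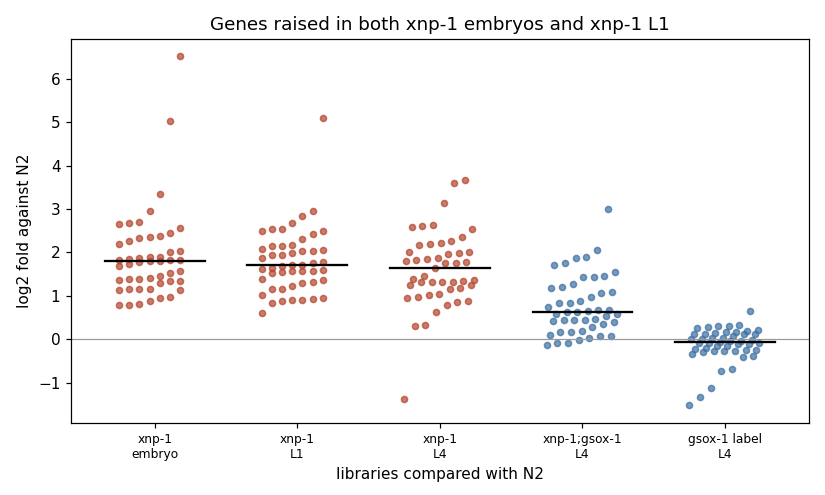
Log2 fold change against N2 of the 49 genes raised in both xnp-1 embryos and xnp-1 L1 larvae (points, 47 of them tested at L4), with bars at the medians, in 5 comparisons. The L4 medians are 1.65 for xnp-1, 0.64 for xnp-1;gsox-1 and -0.05 for libraries labelled gsox-1, and the genes were chosen for their rise in the first 2 comparisons.

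From N2 embryos to N2 L1 larvae, the reference for normal development here, 6063 genes rose and 4460 fell (edgeR). The cuticle collagen gene col-80 was at least 4600-fold higher, and col-142, phat-7, col-42, scl-5 and linc-44 rose by 9.54 (SE 0.934), 8.39, 8.25 (1104 against 3.63 CPM), 8.23 and 8.02. In N2 embryos col-142 had 1 count and scl-5 had 4, so the size and rank of their rise are uncertain. fbxb-81, pes-10, skr-15, fbxb-71, fbxb-119 and sdz-16 changed by -2.52, -2.41, -2.40, -2.34, -2.29 and -2.24. xnp-1 and gsox-1 fell by 0.69 and 0.77 (edgeR adjusted p = 0.0013 and 0.00405). Neuropeptides (99 of 105 rose, median 2.52), intracellular pathogen response genes (36 of 43), chemoreceptors (219 of 364, 14 fell), innate immunity genes (25 of 34), and ribosomal proteins (67 of 80) rose as lists. So did starvation genes (16 of 23), xenobiotic genes (22 of 35), neurotransmitter identity genes (19 of 28), collagens (64 of 148, 13 fell) and intestine genes (16 of 25). Early embryonic fate genes (24 of 33 fell), oocyte (21 of 25), DNA damage (23 of 35), histones (19 of 28) and synMuv B genes (15 of 17) fell, as did meiosis (15 of 28), Argonaute (25 of 45), dosage compensation (14 of 19), heterochromatin (14 of 17), P granule (13 of 20), hypodermis (14 of 21) and moulting genes (22 of 48). Camera adjusted p ran from 2.18e-23 to 0.0238 over these 22 lists, and none held with an estimated correlation (the lowest, for neuropeptides, adjusted p = 0.441 with an estimated correlation).

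At L4, libraries labelled xnp-1 stood apart from N2 with yolk, oocyte and several collagen genes higher and other collagen and cuticle genes lower. The collagen gene col-95 (WBGene00000670, chromosome III, 11703994 to 11705091) rose by 12.27 (log2, SE 0.567), to 96.0 CPM against 0.0166 in N2 (n = 3 each), col-143 by 10.44 (1140 against 0.815 CPM) and col-8 by 9.28 (1488 against 2.396 CPM). The transthyretin-related gene ttr-42 was at least 1200-fold higher, lsy-27 at least 732-fold, the Skp1-related gene skr-7 at least 424-fold and ssp-37 at least 356-fold, with no count in N2. ule-1, the T-box gene sea-1, pzf-1, btb-6 and col-135 rose by 10.75, 10.53, 10.18, 9.50 and 8.95. In N2, sea-1, pzf-1 and btb-6 had 1 count each, col-95 had 2 and col-135 had 4, so the size of these rises is uncertain. gtnt-17, gtnt-18, gtnt-14 and gtnt-31 changed by -6.28 (SE 0.55), -6.24, -5.52 and -5.33. The collagen genes col-47, col-110, col-79, bli-2 and lon-3 changed by -5.95, -5.49 (7.73 against 348.2 CPM), -5.48, -5.28 (30.0 against 1162 CPM) and -5.08, and the cuticlin gene cut-3, spia-1 and the UDP-galactopyranose mutase gene glf-1 by -5.24, -5.09 and -5.01. In all, 4071 genes rose and 4421 fell (edgeR). Without any single library the count stayed between 6847 and 7974.

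Oocyte, P granule, meiosis and Argonaute lists rose in the L4 libraries labelled xnp-1, and the germline lists of sperm genes and ERI pathway targets were not called. All 25 oocyte genes rose (median 4.39; 25 adjusted over the list alone, camera adjusted p = 2.74e-17 and adjusted p = 0.211 with an estimated correlation). Among them were the eggshell genes egg-2 at 4.17 (SE 0.173), egg-3 at 3.84 and cpg-2 at 4.96 and the maternal RNA regulator pos-1 at 5.64. All 6 vitellogenin genes, which encode yolk proteins, rose (6 adjusted over the list alone; median 6.23, vit-1 at 5.03, vit-2 at 6.39, camera adjusted p = 0.000123 and adjusted p = 0.267 with an estimated correlation). All 28 meiosis genes rose (28 adjusted over the list alone; median 1.503; zim-2 at 2.33, spo-11 at 2.14, camera adjusted p = 1.5e-12 and adjusted p = 0.0757 with an estimated correlation). So did 33 of 34 DNA damage and replication genes (median 1.40, mcm-3 at 1.99, pcn-1 at 1.84), and 18 of 20 P granule genes (1.88, nos-2 at 6.48, meg-4 at 6.64). Risen too were 16 of 17 synMuv B genes (1.34), 15 of 17 heterochromatin factors (1.20), 9 of 19 dosage compensation genes (0.75), 24 of 39 intracellular pathogen response genes (1.94, eol-1 at 5.31, pals-14 at 4.31) and 5 of 20 heat shock genes (0.60). These lists had camera adjusted p from 1.54e-14 to 0.0399 and adjusted p from 0.208 to 0.461 with an estimated correlation. Of 46 Argonaute genes 31 rose and 3 fell, or 33 and 3 adjusted over the list alone (median 0.97, vsra-1 at 4.57, camera adjusted p = 2.82e-07 and adjusted p = 0.443 with an estimated correlation).

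Cuticle collagen, moulting and ribosomal lists fell in the same libraries. Of 160 collagen genes 87 fell and 32 rose, or 89 and 32 adjusted over the list alone (median -2.001, mean -0.89, camera adjusted p = 0.00028 and adjusted p = 0.477 with an estimated correlation). Of 48 moulting genes 31 fell and 3 rose (median -2.32, mlt-8 at -4.30, wrt-1 at -4.86, camera adjusted p = 3.01e-06 and adjusted p = 0.257 with an estimated correlation). Of 81 ribosomal protein genes 40 fell and 2 rose, or 42 and 2 adjusted over the list alone (median -0.62, camera adjusted p = 4.9e-07 and adjusted p = 0.443 with an estimated correlation). Of 105 neuropeptides 39 fell and 2 rose, or 34 and 2 adjusted over the list alone (median -0.58, nlp-30 at -2.96, camera adjusted p = 7.38e-05 and adjusted p = 0.224 with an estimated correlation). Intestine (10 of 25 fell), histone (13 of 30 fell) and xenobiotic genes (14 of 33 fell, 3 rose) fell with camera at adjusted p from 0.0183 to 0.0271, and with an estimated correlation at adjusted p from 0.208 to 0.603. Sperm genes were not called (21 of 65 fell, 4 rose; median -0.46, camera adjusted p = 0.109). Camera did not call the lists of body wall muscle (6 of 25 fell), pharynx (6 of 19), pan-neuronal (10 of 27), neurotransmitter identity (9 of 28), sensory cilia (7 of 29), chemoreceptor (13 of 113), glia (4 of 15), hypodermis (6 of 22), coelomocyte and vulval (6 of 12), flavin monooxygenase (7 of 22) and innate immunity genes (11 of 35). It did not call starvation genes (6 of 23 rose), early embryonic fate genes (median -0.21, mean 0.59; 6 of 19 rose, 2 fell), ERI pathway targets (2 of 8 rose) or histone H3.3 and its partners (3 of 8 rose, 3 fell; median -0.05, and 0.04 with size factors). Camera adjusted p for these lists ran from 0.052 to 0.903.

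**Figure D3:**
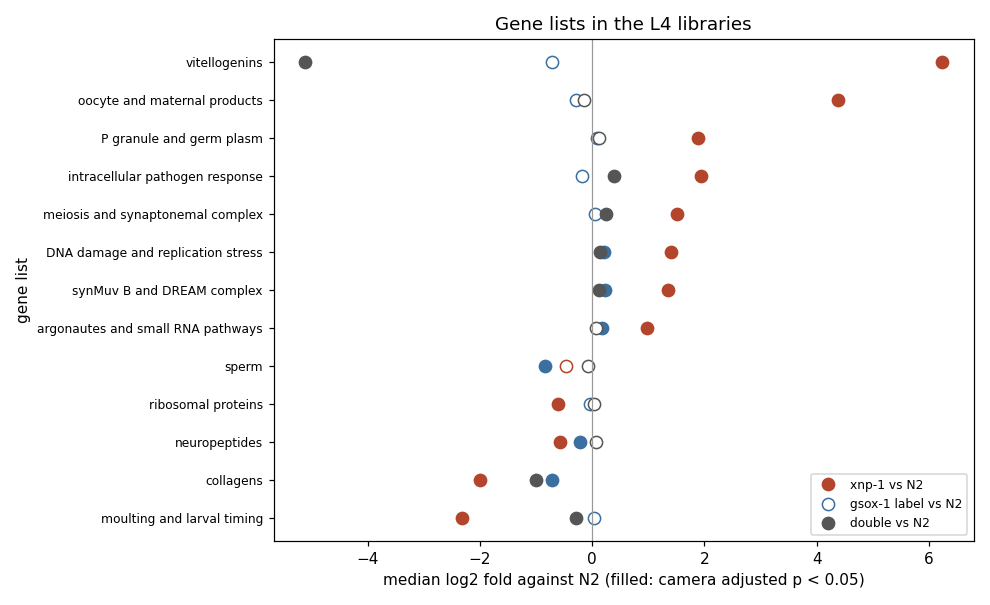
Median log2 fold change against N2 of 13 gene lists (y axis) in 3 L4 comparisons (colours), filled where camera gave an adjusted p under 0.05. In xnp-1 libraries vitellogenins have a median of 6.23 and oocyte genes 4.39, and in xnp-1;gsox-1 libraries vitellogenins have -5.11; the sperm median of xnp-1;gsox-1 changes sign with the scaling, and none of these calls held with an estimated correlation.

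L4 libraries labelled gsox-1, in which the gsox-1 transcript was not reduced, differed from N2 in 4 genes. F56A4.3 (WBGene00018911, chromosome V, 2453414 to 2456147) was lower (-10.40, SE 0.732; 0.142 ± 0.103 against 193.4 ± 97.9 CPM, SD, n = 3 each; edgeR adjusted p = 0.000155). Lower too were scb-1 (-2.23, SE 0.218; 5.41 ± 1.42 against 25.4 ± 3.66 CPM; adjusted p = 0.00258, edgeR) and the cuticlin-like gene cutl-20 (-2.08, adjusted p = 0.0494, edgeR). The chemoreceptor gene srw-85 was higher (3.72, SE 0.498; 6.01 against 0.453 CPM; edgeR adjusted p = 0.048). Sperm genes fell as a list (median -0.83, 0 of 65 called over all genes or adjusted over the list alone, camera adjusted p = 1.69e-21 and adjusted p = 0.821 with an estimated correlation). Also lower were collagens (median -0.72, -0.71 with bounds; 0 of 160, camera adjusted p = 2.13e-09 and adjusted p = 0.821 with an estimated correlation) and neuropeptides (-0.22). DNA damage (0.20), Argonaute (0.18), heterochromatin (0.24), hypodermis (0.29), synMuv B (0.23), body wall muscle (0.20), dosage compensation (0.31) and pan-neuronal genes (0.18) rose. Camera adjusted p for these lists ran from 4.48e-05 to 0.0343 and adjusted p = 0.821 to 0.822 with an estimated correlation. No member of these lists was called by edgeR, where 858 genes of all lay at an unadjusted p under 0.05. The count was 2 without gsox-1 replicate 1, without gsox-1 replicate 2 or without N2 replicate 2. It was 55 with DESeq2, 1 in a fit of these groups alone and 14 without the L4 libraries of highest mitochondrial share.

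L4 libraries labelled xnp-1;gsox-1 differed from N2 in 182 genes (75 higher, 107 lower; edgeR). snpc-1.2 (WBGene00012715, chromosome III, 13165659 to 13169541) rose by 1.72 (SE 0.148) to 100.8 ± 9.79 CPM against 30.7 ± 3.14 (SD, n = 3 each), and the Argonaute gene vsra-1 by 1.86 (SE 0.297; 52.99 against 14.6 CPM). srw-85, vet-2, the P granule gene meg-4, fbxa-170, bath-45, tsp-1, the insulin-like gene ins-35, ddn-1, his-32 and the scramblase gene scrm-4 rose by 4.51, 3.27, 2.80, 2.22, 2.05, 1.98, 1.82, 1.75, 1.74 and 1.64. The yolk genes vit-2 and vit-1 changed by -4.72 (SE 0.988) and -3.41 (SE 0.394; 5.95 ± 2.03 against 63.5 ± 28.8 CPM), and cut-3 by -4.15. oac-1 changed by -3.36, the acid sphingomyelinase gene asm-3 by -2.53 and nspc-14, nspc-10, nas-20, vrp-1, nceh-1, clec-60 and col-68 by -2.36, -2.20, -2.19, -2.09, -2.08, -1.88 and -1.87. The numbers pair these libraries, and a fit of both groups alone with the replicate block called 1637 genes (569 higher, 1068 lower), among them 174 of the 182. There fbxa-170, vit-2 and nas-20 missed the threshold (adjusted p = 0.0656, 0.0772 and 0.0962, edgeR), and with the block in the fit of all groups tsp-1 and ins-35 did (adjusted p = 0.076 and 0.0501, edgeR).

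Collagens fell in xnp-1;gsox-1 libraries (4 of 160 over all genes, and 51 lower and 1 higher adjusted over the list alone). col-64 was at -3.29, col-148 at -5.16 and col-132 at -4.05, and the list median was -1.01 (camera adjusted p = 4.87e-08 and adjusted p = 0.596 with an estimated correlation). Vitellogenins fell (2 of 6, and 6 adjusted over the list alone; median -5.11, camera adjusted p = 7.19e-05 and adjusted p = 0.596 with an estimated correlation). Meiosis genes rose (1 of 28, syp-1 at 0.78, and 2 adjusted over the list alone; median 0.25, camera adjusted p = 0.000621 and adjusted p = 0.596 with an estimated correlation). DNA damage (median 0.14), intracellular pathogen response (0.39), ERI pathway (0.36), synMuv B (0.12) and heterochromatin lists (0.20) rose, and moulting (-0.29, nas-36 called at -1.12) and histone lists (-0.33) fell. Camera adjusted p ran from 0.00226 to 0.0433 and adjusted p from 0.596 to 0.904 with an estimated correlation. Scaled by library totals, the medians were 0.22 for DNA damage and 0.21 for synMuv B genes. With the replicate block the heterochromatin and histone calls were lost (camera adjusted p = 0.0584 and 0.0645). The count of genes was 44 without xnp-1;gsox-1 replicate 2, 61 without its replicate 3, 78 without N2 replicate 2 and 73 without N2 replicate 3. It was 811 with DESeq2 and 1 in an unpaired fit of both groups alone.

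Against libraries labelled xnp-1, those labelled xnp-1;gsox-1 had 3896 genes higher and 3835 lower (edgeR). Of the 11 lists that rose in xnp-1 libraries 10 were lower here by camera, and heat shock genes were not called (1 rose and 4 fell of 20, camera adjusted p = 0.231). vit-5, vit-4 and vit-3 changed by -13.50 (SE 2.313; 0.306 against 3651 CPM, n = 3 each), -12.70 (0.146 against 1016) and -12.69 (0.121 against 818.5). skr-7, btb-6 and clec-97 were at least 459-fold, 356-fold and 351-fold lower, with no count in xnp-1;gsox-1. srw-85, col-47, gtnt-18, dpy-7, gtnt-17 and srf-5 rose by 7.65 (SE 0.651), 6.54, 5.84, 5.66 (584.2 against 11.5 CPM), 5.64 and 5.48. gsox-1 was lower (-1.21, edgeR adjusted p = 0.00217), as was xnp-1 (-0.65, edgeR adjusted p = 0.0235). All 25 oocyte genes fell (25 adjusted over the list alone; median -4.36, camera adjusted p = 1.73e-18 and adjusted p = 0.214 with an estimated correlation). Also lower were 33 of 34 DNA damage genes, 26 of 28 meiosis genes, 18 of 20 P granule genes, 14 of 17 synMuv B genes, 28 of 46 Argonaute genes, 13 of 17 heterochromatin factors, 6 of 6 vitellogenins (median -11.93), 18 of 39 intracellular pathogen response genes and 9 of 19 dosage compensation genes. Of 81 ribosomal protein genes 45 rose, with 47 of 105 neuropeptides, 26 of 48 moulting genes and 12 of 33 xenobiotic genes. Camera adjusted p for these 14 lists ran from 1.73e-18 to 0.0266, and adjusted p from 0.12 to 0.49 with an estimated correlation. Collagens went both ways (62 rose, 32 fell; median 0.52, mean -0.12, camera adjusted p = 0.0885).

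Of the 8492 genes changed in L4 libraries labelled xnp-1, 137 (1.61%) were changed the same way in those labelled xnp-1;gsox-1 against N2 and 13 the opposite way. For 6609 of them (77.8%) the libraries labelled xnp-1;gsox-1 differed from the xnp-1 libraries against the direction of the xnp-1 change, by the test between both groups. For 12 they differed along it. Genes that moved past N2 are counted too, such as vit-1, which was higher than N2 in xnp-1. In xnp-1;gsox-1 it was lower than N2 (5.95 against 63.5 CPM, edgeR adjusted p = 0.00242). By the interaction test 5411 (63.7%) went against the direction of the xnp-1 change and 4 along it. Both tests use the xnp-1 libraries by whose change the genes were picked. Part of the move against that change thus comes from the choice in each, and the size of that part is not known. The median change was 1.39 in xnp-1 and 0.11 in xnp-1;gsox-1 for the higher genes, and -1.52 and -0.18 for the lower genes. With DESeq2 calls the share also changed was 6.06%. The replicate numbers pair N2 and xnp-1;gsox-1 libraries, and the paired fit given above called more genes. The share was not computed from that fit.

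The interaction, which asks whether the xnp-1 label goes with another change when the gsox-1 label is present, called 5826 genes at L4 (3007 higher, 2819 lower; edgeR). col-47, gtnt-18, gtnt-17, col-110, col-79 and dpy-7 had interaction values of 6.45 (SE 0.936, edgeR adjusted p = 0.000597), 6.22, 6.08, 5.38, 5.34 and 5.30, and vit-5, vit-3 and vit-4 of -12.31, -12.07 and -11.96. skr-7, ttr-42 and clec-97 had fitted values of -15.88, -11.95 and -10.86 that are no bounds, since groups stood at or near 0 counts. xnp-1 and gsox-1 themselves had -0.94 (adjusted p = 0.0278, edgeR) and -1.67 (adjusted p = 0.00407, edgeR). Oocyte (25 of 25), DNA damage (30 of 34), meiosis (23 of 28), P granule (18 of 20), Argonaute (23 of 46), synMuv B (13 of 17), heterochromatin (13 of 17), vitellogenin (6 of 6) and dosage compensation lists (9 of 19) fell. Ribosomal (29 of 81), neuropeptide (34 of 105), sperm (21 of 65), moulting (22 of 48), collagen (62 of 160, 22 fell) and xenobiotic lists (11 of 33) rose. Camera adjusted p ran from 1.36e-18 to 0.0216 over these 15 lists, and adjusted p from 0.148 to 0.523 with an estimated correlation.

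Against libraries labelled gsox-1, those labelled xnp-1;gsox-1 had 71 genes higher and 43 lower (edgeR). xnp-1 was lower (29.3 against 92.2 CPM; -1.65, SE 0.21, edgeR adjusted p = 0.00433). bath-45 rose by 2.39 (SE 0.327), cutl-20 by 2.22, rnh-1.3 by 2.15, tsp-2 by 2.07, scrm-4 by 1.84 and the sperm protein gene msp-65, whose family can share reads, by 2.47. vit-1 changed by -3.85 (SE 0.402; 5.95 against 85.6 CPM, n = 3 each), clec-70 by -3.20, asm-3 by -2.83, clec-60 by -2.55, math-38 by -2.54 and clec-71 by -2.53. Sperm genes rose (1 of 65 over all genes, 5 adjusted over the list alone; median 0.73, camera adjusted p = 1.35e-11 and adjusted p = 0.603 with an estimated correlation). Vitellogenins fell (1 of 6, and 6 adjusted over the list alone; median -4.19, camera adjusted p = 0.000767 and adjusted p = 0.602 with an estimated correlation). Intracellular pathogen response (0.45), ERI pathway (0.72), neuropeptide (0.27) and meiosis genes (0.17) rose, and body wall muscle (-0.37), pan-neuronal (-0.28), moulting (-0.41) and dosage compensation genes (-0.45) fell. Camera adjusted p ran from 0.000682 to 0.0468 and adjusted p from 0.602 to 0.634 with an estimated correlation. Leaving out xnp-1;gsox-1 replicates 2 and 3 in turn gave 53 and 73 genes, and leaving out gsox-1 replicates 1, 2 and 3 gave 38, 39 and 51. The count was 531 with DESeq2, 23 in a fit of both groups alone, 300 (161 higher, 139 lower) without the L4 libraries of highest mitochondrial share, and 107 higher and 40 lower with library totals (72.8% higher, against 62.3%).

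Overlaps among the L4 comparisons share the N2 libraries, and N2 has 3 libraries, so the controls could not be divided between comparisons. Of the genes that rose in xnp-1 libraries, 68 also rose in xnp-1;gsox-1 libraries (17.5 expected if independent), and 69 fell in both (27 expected), with 13 in opposite directions (Fisher's exact tests, two-sided, adjusted p = 1.51e-34 and 2.78e-17). The log2 changes had a correlation across genes of 0.332 and a covariance of 0.526, against 0.504 (0.475 to 0.523) and 0.128 in 20 simulated sets of unchanged groups, where no gene was called in both. That simulation covered xnp-1 and xnp-1;gsox-1 only and drew each library independently. It lacks the structure that same-numbered N2, xnp-1 and xnp-1;gsox-1 libraries share. How much of the covariance or of the shared calls comes from that structure is thus not known. For gsox-1 and xnp-1;gsox-1, 1 gene rose in both (0.00429 expected) and none fell in both (0.0184 expected), with a correlation of 0.503 and a covariance of 0.28. For xnp-1 and gsox-1, none rose in both (0.233 expected), 2 fell in both (0.758 expected) and 1 went in opposite directions, with a correlation of 0.191 and a covariance of 0.229. Where more genes were shared than expected, part of that may come from the shared controls. Between separate fits, 61 genes rose and 58 fell in both xnp-1 embryos and L4 xnp-1 (18.1 and 27.6 expected, adjusted p = 3.05e-25 and 1.6e-09, Fisher's exact test), with 9 in opposite directions. Likewise 54 rose and 13 fell in both L1 and L4 xnp-1 (15.4 and 4.76 expected, adjusted p = 2.36e-24 and 0.000142, Fisher's exact test), with 4 in opposite directions.

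The X chromosome held fewer risen genes than its share of the genes tested in xnp-1 embryos, L1 and L4 libraries, and more fallen genes than its share at L4. In xnp-1 embryos 2 of 76 risen genes lay on X (2.6%, against 14.6% of genes tested; odds ratio 0.157, adjusted p = 0.00366) and 4 of 121 fallen genes (odds ratio 0.198, adjusted p = 0.00032). Chromosome V held 49 of the fallen genes (40.5% against 22.4%; odds ratio 2.38, adjusted p = 3.71e-05). In L1 larvae 2 of 64 risen genes lay on X (odds ratio 0.187, adjusted p = 0.0134), and 0 of 21 fallen genes did (adjusted p = 0.14). In L4 xnp-1 libraries X held 378 of 4071 risen genes (odds ratio 0.547, adjusted p = 1.16e-25) and 738 of 4421 fallen genes (odds ratio 1.29, adjusted p = 8.24e-07), and chromosome I held 802 of the risen genes (odds ratio 1.45, adjusted p = 2.29e-14). These are two-sided Fisher's exact tests adjusted over 96.

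The table named for 22G-RNAs was compared in the same way, as planned, although its columns follow the poly(A) counts. In xnp-1 embryos 120 features were higher and 218 lower (edgeR), led by F15D4.5 (2.97), C48B4.10 (2.66), C30G12.6 (2.57), sdha-2 (2.41), Y46G5A.43 (2.33) and F22D6.9 (2.21), and by nspg-7.2 (-3.06), clec-15 (-2.96), clec-13 (-2.91), pgp-9 (-1.97), srbc-15 (-1.97) and clec-50 (-1.89). In L1 larvae 112 were higher and 86 lower, led by C30G12.6 (2.74), F15D4.5 (2.69), sdha-2 (2.55), C06A1.4 (2.43), Y46G5A.43 (2.20) and bath-29 (1.99), and by srbc-15 (-1.86), F56A4.8 (-1.79), irld-53 (-1.76), irld-35 (-1.75), F56A4.2 (-1.68) and clec-209 (-1.67). The difference between stages called 0 features with edgeR (1142 at an unadjusted p under 0.05) and 7 with DESeq2. Across 16769 genes in both tables, where genes are not independent replicates, the changes correlated with the poly(A) changes at Pearson 0.778 and Spearman 0.877 in embryos and 0.906 and 0.926 in L1 (permutation p = 1e-05 for each, the smallest that 100000 resamples can give). Of the genes called in either table, 157 embryo genes and 64 L1 genes were called in both, all in the same direction. Because the columns follow the poly(A) counts, neither these correlations nor the shared calls test anything about small RNAs. The embryo count was 128, 217 and 163 without N2 replicates 1 to 3 and 196, 160 and 188 without xnp-1 replicates 1 to 3. The L1 count was 84 without N2 replicate 2, 58 higher and 61 lower without N2 replicate 1, and 123, 107 and 92 without xnp-1 replicates 1 to 3. DESeq2 called 881 and 413.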

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

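Chosen only after the result was seen were the test of when the lower embryo genes rise in N2, the age score as a covariate (its bound was set when the calls that stayed with it were known), the test of the xnp-1 level for an intact gene, and the match of the table named for 22G-RNAs to poly(A) libraries. For 2 further readings, named where they stand, the rule was made stricter after the values were known.

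The effect that goes with the xnp-1 label at L4 differed with and without the gsox-1 label, by the test of the difference itself, for 5826 genes. Among the named genes the interaction was 6.45 for col-47, 6.22 for gtnt-18, 6.08 for gtnt-17, 5.38 for col-110, 5.34 for col-79 and 5.30 for dpy-7. It was -12.31 for vit-5, -12.07 for vit-3 and -11.96 for vit-4, and fitted values for skr-7 (-15.88), ttr-42 (-11.95) and clec-97 (-10.86) rest on groups at or near 0 counts. The interaction was -0.94 for xnp-1 and -1.67 for gsox-1.

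In L4 libraries labelled xnp-1, oocyte and vitellogenin genes rose (medians 4.39 and 6.23) and moulting genes fell (-2.32). In libraries labelled xnp-1;gsox-1 oocyte genes were not called (-0.15, camera adjusted p = 0.465), vitellogenins fell (-5.11) and moulting genes fell less (-0.29). Over all genes, edgeR called only vit-1 and vit-2 of those vitellogenins and nas-36 of those moulting genes. None of these list calls held with an estimated correlation. One candidate explanation is that the xnp-1 animals were older at harvest: the leading component of the spread within the other 3 groups correlated across genes with the change between xnp-1 and gsox-1 libraries at 0.086, under the bound of 0.2 set beforehand for an answer of no. That bound was wrong, since 62.8% of this component (42.4% of the spread over 9 libraries) lies in the 2 libraries of highest mitochondrial share and so need not follow age. The next component (23.2% of the spread, 2.7% of it in those 2 libraries) correlated at 0.002, but the bound did not name it, and no value ties either component to age. Another is that these libraries came from animals with an intact xnp-1 gene: xnp-1 was lower by more than 2 SE (-0.72), but 31.2% of genes tested changed by as much or more in that direction, a comparison added after the value was known. Of the genes raised in both xnp-1 embryos and L1, 41 of 47 were also higher here (median 1.65, against -0.57 to 0.30 in random sets), and of those lowered 9 of 11 were lower (median -2.15), which runs with the label. These values do not exclude an intact gene, since animals that differ in age could differ in these genes too, which was not tested. Neither explanation can be told apart from an effect of the genotype, since each group is 1 set of 3 libraries and the labels give no age beyond the stage.

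Genes lower in xnp-1 embryos tend to rise later in normal development. Their median change from N2 embryos to N2 L1 was 1.07, against 0.10 for all genes and -0.16 to 0.43 in random sets of as many genes (permutation p = 1e-05, the smallest that 100000 sets can give; 78 of 121 rose and 7 fell), which is consistent with xnp-1 embryos that were younger on average. An age score was lower by 0.37 in xnp-1 embryos (0.20 without xnp-1 replicate 1) and by 0.35 in xnp-1 L1, against a rise of 3.04 from N2 embryos to N2 L1. In L1, where the numbers pair the libraries, it was lower in 3 of 3 pairs (by 0.54, 0.24 and 0.27). Leaving out single L1 libraries breaks a pair, and gave 0.09 higher without N2 replicate 1. It gave 0.10, 0.64 and 0.70 lower without xnp-1 replicate 3, N2 replicate 3 and xnp-1 replicate 1. The score's genes were picked by the difference between these same N2 groups, so the rise of 3.04 follows from the choice. The choice tends to raise the score of N2 L1 and to lower that of N2 embryos. Part of the gap in L1, in the pairs too, may come from it. In embryos it works against the gap. With that score as a covariate the lower genes kept 89.7% of their median change, and 121 of 121 stayed called. Their median was -1.61 before and -1.44 after (median SE 0.283 and 0.23). The covariate has a single slope for embryo and L1 libraries, set by the spread within groups. The centred score ran from -0.41 to 1.05 in N2 L1 and from -0.68 to 0.51 in xnp-1 L1. It ran from 0.08 to 0.36 in N2 embryos and from -0.51 to -0.01 in xnp-1 embryos. The slope thus rests mostly on L1 and need not hold for embryos, so this does not decide whether age is the whole cause. Genes higher in xnp-1 embryos had a median of 0.069 from N2 embryos to L1 (p = 0.4, permutation; 18 rose and 14 fell), which decides nothing. With the score as a covariate they kept 92.7% of their median change, and 76 of 76 stayed called, where 659 genes were called in place of 197. Their median was 1.55 before and 1.44 after (median SE 0.226 and 0.195). For the same reason this does not decide whether age is the whole cause for them. An age difference as a part or the whole of the cause and the genotype stay open for both sets. Each list that rose in xnp-1 embryos had a median below 0 from N2 embryos to N2 L1, such as histones (-1.23) and DNA damage genes (-0.87). Each list that fell had one above 0, such as neuropeptides (2.52), but for moulting genes (-0.76). Body wall muscle genes (0.12) lay close to all genes. An age difference thus stays open for these lists too.

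The table named for 22G-RNAs may hold counts of the poly(A) reads. In 12 of 12 columns the best match was the poly(A) library of the same genotype, stage and number (correlation across 10451 genes 0.980 to 0.989, at most 0.970 with any other library), at a median ratio of 2.04 to 2.07. No biological explanation was tested for this match. Whether the same reads were counted in another way or another file was deposited under this name was not tested.

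Other splits of the same libraries were fitted as well. For the comparisons of 3 libraries with 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other gave 197 and 0 genes for embryos, 85 and 0 for L1, 10523 and 0 for N2 L1 against embryos, 8492 and 0 for L4 xnp-1, 4 and 38 for gsox-1, 182 and 1495 for xnp-1;gsox-1, 7731 and 0 for xnp-1;gsox-1 against xnp-1, 114 and 0 against gsox-1, and 338 and 22 and 198 and 0 for embryos and L1 in the table named for 22G-RNAs. As many genes as the real split came from 2 of the 10 splits for gsox-1 and for xnp-1;gsox-1, and from 1 of 10, the real one, in the others. The split with 1495 genes sets N2 replicate 1 with xnp-1;gsox-1 replicates 1 and 2, which points to a structure of the samples. Replicate numbers pair these libraries, and the other splits that part all 3 pairs called none, by edgeR. The split with 38 genes sets N2 replicate 3 with gsox-1 replicates 1 and 2. For the L4 interaction 2 of 40 splits gave as many genes, the real one with 5826 and another with 6087. That other split keeps the 4 groups whole and sets gsox-1 with N2 against the rest, so it compares the groups themselves. The 4 drawn splits that part xnp-1 from N2 and mix gsox-1 with xnp-1;gsox-1 gave 4883 to 5593, and the other 34 gave 0. The count thus goes with the parting of xnp-1 from N2 more than with that of xnp-1;gsox-1 from gsox-1, and the share decides nothing about chance. For the differences between stages the real count is 0, so 40 of 40 splits give as many whatever the data (at most 22, and at most 18 in the table named for 22G-RNAs), and this says nothing about chance.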

How the results depend on the processing

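The age score, the replicate block with only the groups compared, and leaving out the 2 L4 libraries of highest mitochondrial share were chosen after seeing the data. Of the counts of changed genes, 152 alternatives stayed within 1.5 times and 58 did not. Values of named genes stayed on their side of the threshold with their direction in 2136 cases, lost the call in 290, gained it in 2 and moved without a call in 6. Single lists kept their call or its absence in 1102 cases, lost it in 223, gained it in 22 and turned without a call in 13. The cause was not tested unless given. Only the groups compared means fewer libraries behind the spread, and it equals the fit used for the interactions and gives no value of its own there.

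DESeq2 called 590 genes for embryos, 234 for L1, 3 for the stage difference, 55 for gsox-1, 811 for xnp-1;gsox-1, 531 for it against gsox-1, and 881, 413 and 7 for embryos, L1 and the stage difference in the table named for 22G-RNAs. A fit of only the groups compared called 580, 13, 1 (gsox-1), 1 (xnp-1;gsox-1), 23 (xnp-1;gsox-1 against gsox-1), and 592 and 22 in the table named for 22G-RNAs. The age score gave 659 and 245. A fold minimum of 1 log2 gave 6685 for N2 L1 against embryos. Without the libraries of highest mitochondrial share, gsox-1 gave 14 and xnp-1;gsox-1 against gsox-1 gave 300. xnp-1 in L1 passed the threshold with DESeq2 (-0.55), the age score (-0.56) and the block with only the groups compared (-0.55), but not with the block alone (-0.54, adjusted p = 0.0965, edgeR), and xnp-1 in xnp-1;gsox-1 did not in a fit of only the groups compared (-1.34, adjusted p = 0.122, edgeR).

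The replicate block gave 337 genes for embryos (90 higher, 247 lower), where numbers do not pair the libraries (-0.01, 0.146 and -0.161, and 1 of 3 libraries correlates best with its own number), a count within 1.5 times for L1, 0 for the stage difference (edgeR, 631 at an unadjusted p under 0.05), 11113 for N2 L1 against embryos, 8967 for L4 xnp-1, 2 for gsox-1 (numbers unpaired, 0 of 3), 176 for xnp-1;gsox-1, 8265 and 135 for it against xnp-1 and gsox-1, 6414 for the interaction, and 525, 264 and 0 in the table named for 22G-RNAs. The block with only the groups compared gave 2002 for L1 and 1637 for xnp-1;gsox-1, where the numbers pair the libraries. Camera with the block called 19, 17, 9, 22, 18, 11, 8, 14, 11 and 15 lists. Where numbers do not pair the libraries, acox-1.4 in embryos and srw-85 and cutl-20 in gsox-1 missed the threshold with the block (adjusted p = 0.0531, 0.0979 and 0.0944, edgeR), and camera gained heat shock genes in embryos and hypodermis genes in xnp-1;gsox-1 against gsox-1. Where they do, the block changed no call of a named gene or list but those given in the report.

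Leaving out 1 library gave 53 to 157 genes for embryos, 35 to 79 for L1, 0 to 0 for the stage difference, 8041 to 11186 for N2 L1 against embryos, 6847 to 7974 for L4 xnp-1, 2 to 3 for gsox-1, 44 to 187 for xnp-1;gsox-1, 5920 to 7659 and 38 to 125 for it against xnp-1 and gsox-1, 4327 to 6126 for the interaction, and 128 to 217, 84 to 192 and 0 to 0 in the table named for 22G-RNAs. The level of xnp-1 against N2 ran from -0.83 to -0.58 for L4 xnp-1 and from -1.54 to -1.20 for xnp-1;gsox-1. The libraries that moved a count are named with the report's results.

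Camera with an estimated correlation called 0 lists in each of the 10 comparisons, with 0 to 7 lists at an unadjusted p under 0.05 and 9 to 22 called at the preset correlation. Fry called 0 lists for embryos, the stage difference, gsox-1, xnp-1;gsox-1 and xnp-1;gsox-1 against gsox-1 (0 to 7 at an unadjusted p under 0.05) and 1 for L1. It called 25 for N2 L1 against embryos, 22 for L4 xnp-1, 19 for xnp-1;gsox-1 against xnp-1 and 17 for the interaction. Among these were 21 of 22, 18 of 18, 14 of 14 and 13 of 15 camera calls, though fry does not compare a list with other genes. With a fold minimum the odds ratio on X was 0.219 for genes higher in L1, 1.14 for genes lower in L4 xnp-1, 1.04 for genes higher in xnp-1;gsox-1 against xnp-1 and 1.08 for N2 L1, where fewer genes were counted, and that of chromosome III for genes lower in N2 L1 turned to 0.854. With DESeq2 calls the genes changed in both were 152 for embryo and L1, 548 for xnp-1 and xnp-1;gsox-1, 31 for gsox-1 and xnp-1;gsox-1, 29 for xnp-1 and gsox-1, 291 for embryo and L4 xnp-1 and 149 for L1 and L4 xnp-1, and the share of xnp-1 genes also changed in xnp-1;gsox-1 was 6.06%. What depth limits was not tested apart from the spread between replicates, and the simulated changed genes had a mean of at least 50 counts, so recovery below that is not known.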

Other observations

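Chosen after the result was seen were the tests of the shared genes in xnp-1;gsox-1, of neighbouring genes and of the correlation between stages with and without the age score.

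Genes that rose in xnp-1 embryos or L1 larvae often stood next to each other on the chromosome. Of 91 such genes among 17674 with a position, 20 adjacent pairs of tested genes had both members raised, against a mean of 0.463 and a highest of 6 in random sets (permutation p = 1e-05, the smallest that 100000 sets can give). 11 pairs lay on the same strand and 1 pair overlapped. The pairs include the meiotic gene zhp-2 with lotr-1 (chromosome I, 8485810 to 8490938), C30G12.6 with puf-8 (chromosome II, 7292026 to 7298247), mrps-14 with the nuclear RNAi gene nrde-2 (chromosome II, 10240277 to 10247638), lin-13 with C03B8.3 (chromosome III, 7700338 to 7717314) and the run of C48B4.9, C48B4.10 and C48B4.11 (chromosome III, 9562331 to 9566115). Adjacent genes may rise together as units. Pairs 92 or 105 bases apart on 1 strand, such as C30G12.6 with puf-8 and mrps-14 with nrde-2, could be read as single transcription units or could share reads, and neither was tested.

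The changes of xnp-1 in embryos and in L1 larvae, in groups that share no library, correlated across genes at 0.47, which may mean that the same genes changed at both stages. Deviations from the group means alone, with numbers resampled together in all groups, gave -0.007 to 0.153 in 9 resamples. With the age score of each stage as covariates, a test added later, the correlation was 0.278. The score was lower in xnp-1 at both stages, by 0.37 and 0.35, so a shared age difference stays open as a part or the whole of this correlation. Part of the gap in L1 may come from the choice of the score's genes on N2 libraries. The 49 genes raised at both stages had a median change of 0.64 in L4 libraries labelled xnp-1;gsox-1 (43 of 47 above 0, against -0.14 to 0.13 in random sets; permutation p = 1e-05, the smallest possible) and of -0.053 in those labelled gsox-1 (20 of 47 above 0; p = 0.6, permutation). A candidate explanation is that this set follows the xnp-1 label at each stage, with or without the gsox-1 label. Against libraries labelled gsox-1 the same genes had a median of 0.85 in xnp-1;gsox-1 libraries (10 of 47 called higher), and against xnp-1 libraries one of -0.75 (2 higher, 23 lower). The 12 genes lowered at both stages had medians of -2.15 in L4 xnp-1 (9 of 11 called lower) and -1.01 in xnp-1;gsox-1 (2 called lower). Permutation p was 1e-04 and 8e-05 for these medians. In libraries labelled gsox-1 they had -0.15 (1 called lower, 1 of 11 above 0; permutation p = 0.2), and in xnp-1;gsox-1 against gsox-1 -0.56 (1 called higher, none lower; permutation p = 0.002).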
